A study of Mus musculus with 12 samples.

How the data were processed

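Mouse bone marrow cells were profiled by RNA-seq in 4 groups of 3 libraries. Per the labels, normal bone marrow cells (WT) or bone marrow cells carrying a retroviral MLL::AF9 vector (MA9) received either a mock retrovirus or a retrovirus expressing the form of Prdm16 that the labels name sPrdm16. Per the labels, total RNA was taken with RNeasy columns and libraries were made with the Nextera XT kit. How cDNA was made, whether ribosomal RNA was removed and whether strand was recorded are not given in the sources used here. The growth medium in the labels names MA9 cells alone, with 5 ng/ml mouse IL-3.

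The authors deposited 1 table per genotype with an expected count per gene and library, which is an estimated count that need not be whole. Per the submitters' processing notes the genome build was mm10 and the tool DRAGEN, with no version. Both tables held the same 55487 gene identifiers, with coordinates and gene classes, and the values were unscaled, with totals that differed between libraries. Between 5.19% and 10.2% of the values in a library were not whole, and all values were rounded to whole counts here. Because each genotype had its own table, a difference between MA9 and WT mock libraries cannot be told apart from a difference between tables. Levels in the mock groups are therefore given as values with no test. In the comparison of the effect sizes a constant difference between the tables cancels. A difference between mock and sPrdm16 libraries within 1 table does not cancel. Ribosomal, 7SL and other structural RNAs averaged 63.7% of the counts in MA9 mock and 18.2% in MA9 sPrdm16. In WT mock and WT sPrdm16 they averaged 2.25% and 1.72%.

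Totals ranged from 17217159 to 37390945 counts per library. In the MA9 mock libraries nuclear protein-coding genes held 7400875, 7406093 and 3844558 counts, in the MA9 sPrdm16 libraries 19473372, 28169209 and 16905133, and in the WT libraries 16046071 to 17789842. Values in the MA9 mock group, above all in replicate 3, therefore rest on fewer counts. No pair of libraries of 1 group differed by less than sampling noise, since the chi-square per gene was between 3.63 and 138. A count of 0 was taken to allow up to 3 counts per library. Such limits and the intervals of count ratios cover counting error alone, because the reads carry no molecular identifiers. Nothing in the labels says that the replicates came from separate cultures or animals, so p-values measure the spread between these samples, which may be technical.

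Genes were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the default low-count filter (minimum count 10) and robust quasi-likelihood F tests. MA9 and WT were each fitted on their own 6 libraries, and the difference between the sPrdm16 effects was tested as an interaction over all 12 libraries. P-values were adjusted by the method of Benjamini and Hochberg over all genes tested, with a threshold of 0.05, and "rose" and "fell" are used of genes past it. Errors of log2 fold changes are standard errors (SE) derived from the F statistic, and errors of CPM (counts scaled to a fixed library total) are SDs over 3 libraries. Across 47 gene lists, camera of limma 3.58.1 compared the members of a list with all other genes, on log2 CPM with a prior count of 2 and a preset correlation of 0.01, where at least 5 members were tested. The lists held 1239 symbols, of which 1238 matched a gene in the tables. Each list was also tested with a correlation estimated from the data and with fry, and counts of members adjusted over the list alone are given beside those over all genes. Fry asks whether the members changed at all, with no comparison to other genes, so it answers another question than camera. Calls shared by MA9 and WT were compared by 2-sided Fisher's exact tests, and these fits share no library.

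Gene groups, lists, tests and the rule for named genes were fixed before the data were examined. The rule took Prdm16, then the 8 largest rises and 8 largest falls per genotype (4 and 4 for the interaction) among called genes. These needed a mean of at least 5 CPM in the higher group and a symbol that was not a predicted gene, clone or pseudogene name. The rule asked for groups that did not overlap within a genotype, and for the interaction that the gene was tested within both genotypes. It added up to 4 members with the smallest p per called list and every called member of the cytarabine list. Which of these list members the text names was chosen after their values were seen, and some members are not reported here. Genes from snoRNA classes lie within introns of host genes, and without a recorded strand their reads, and those of antisense pairs, cannot be told apart from the host's.

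Alternatives tried were RLE scaling, total counts with no scaling factor, no filter, a filter of 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a test against a fold of 1.5, the replicate number as a block, the 20 most abundant and the mitochondrial genes left out, a fit on all 12 libraries, and each library left out in turn. Chosen after seeing the data were a fit on nuclear protein-coding genes, offsets for GC content and transcript length, thinning to equal protein-coding depth, list tests of the interaction on the 12373 genes tested within both genotypes, and other scalings of the mock levels. GC content and length came from the GENCODE M21 annotation of mm10 and covered 99.8% of the genes tested in MA9 and 99.9% in WT. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

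The tests were tested on simulated counts in which 67, 67 and 66 genes changed by 1.5-, 2- and 4-fold. For the MA9 comparison (14076 genes) edgeR recovered 43.3%, 80.6% and 98.5% of these, and 8.05% of its calls were false. For the WT comparison (13713 genes) the values were 40.3%, 64.2% and 86.4%, with 7.48% false. For the interaction (15433 genes) they were 17.9%, 64.2% and 89.4%, with 8.46% false. DESeq2 gave 14.5%, 17.3% and 19.2% false calls in the same 3 simulations. Changed genes were drawn only from genes with ample expected counts in every library, so recovery of low-count genes was not measured. Both groups of a genotype were otherwise drawn from the same mean per gene, so differences between them in RNA classes were not simulated. Camera called the changed list in each simulation, and called 0 of 46 random lists with either correlation. Counts were drawn independently per gene, so these simulations held no correlation between genes. They cannot show how often camera calls a false list where genes are correlated.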

Results

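RNA-seq libraries were made from mouse bone marrow cells that carried, or did not carry, a retroviral MLL::AF9 fusion gene, and that had then received a mock retrovirus or one expressing sPrdm16. MLL::AF9 joins the chromatin regulator MLL (gene Kmt2a) to AF9 (gene Mllt3) and drives acute myeloid leukaemia. Prdm16 is a zinc-finger transcriptional regulator known from brown fat and from blood stem cells. The stated purpose was to find the molecular basis of chemoresistance driven by sPrdm16, with cytarabine resistance and metabolic reprogramming named in the series title. Cells with the fusion are called MA9 and normal cells WT, and each of the 4 groups had 3 libraries. Total counts per library were 21057167 to 23095420 in MA9 mock and 22340098 to 37390945 in MA9 sPrdm16. They were 18322492 to 18588296 in WT mock and 17217159 to 18823704 in WT sPrdm16.

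The groups differed in which classes of RNA their counts came from. Ribosomal RNA, 7SL and other structural RNAs made up 58.0%, 59.7% and 73.3% of the counts in the 3 MA9 mock libraries (mean 63.7% ± 8.38, SD, n = 3). In the MA9 sPrdm16 libraries they made up 18.2% ± 0.120 (SD, n = 3), and in the WT libraries 1.41% to 2.46%. Mitochondrial ribosomal RNA alone was 42.4% ± 5.81 in MA9 mock (SD, n = 3) and 10.9% to 11.2% in MA9 sPrdm16. Nuclear protein-coding genes held 28.2% ± 8.64 of the counts in MA9 mock, 75.5% ± 0.168 in MA9 sPrdm16, 92.5% ± 1.02 in WT mock and 93.9% ± 0.655 in WT sPrdm16 (SD, n = 3 each). MA9 mock replicate 3 stood apart from its group, with 3844558 nuclear protein-coding counts against 7400875 and 7406093. Its chi-square per gene against replicates 1 and 2 was 138 and 112, while these differed from each other by 24.6.

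**Figure D1:**
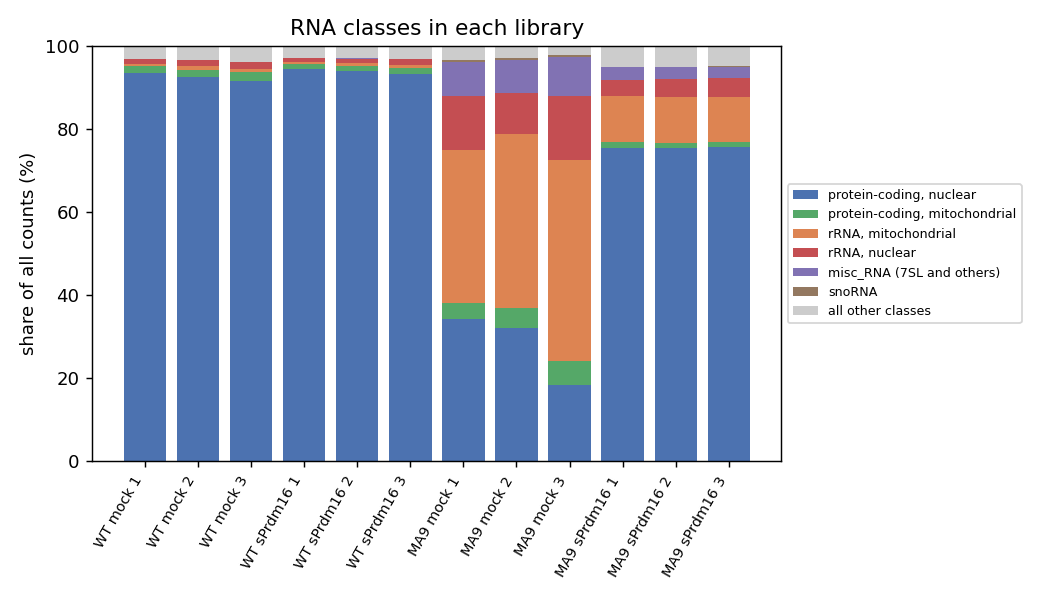
Share of all counts (%, vertical axis) by RNA class in each of the 12 libraries (horizontal axis), with 1 stacked bar per library and 1 colour per class. Nuclear protein-coding genes take 18.3% to 34.2% of the counts in the 3 MA9 mock libraries and at least 75.3% in each other library.

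Prdm16 followed the labels in all 12 libraries. The gene (ENSMUSG00000039410.16) spans chromosome 4, positions 154316125 to 154636873 in mm10. It had 0 counts in each MA9 mock library, which allows up to 0.365 CPM on the scale of the MA9 fit, and 5733, 8889 and 5353 counts in the MA9 sPrdm16 libraries. On that scale this was 140 ± 5.01 CPM (SD, n = 3), at least 383-fold higher than in mock. In WT cells it had 22, 18 and 0 counts with mock and 950, 708 and 793 with sPrdm16. WT levels were 0.769 ± 0.674 and 43.2 ± 4.36 CPM (SD, n = 3 each), a log2 fold change of 5.80 (SE 0.44, edgeR adjusted p = 1.7e-07). Counts from the vector and from the genomic locus were not separated in this gene.

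Kmt2a, the first partner of the fusion, stood at 1719 ± 60.1 CPM in MA9 mock and 1460 ± 56.3 CPM in MA9 sPrdm16, against 58.5 ± 4.37 and 41.5 ± 1.20 CPM in the WT groups (SD, n = 3 each, scaled over all 12 libraries). Counts from the fusion vector and from the genomic Kmt2a locus were not separated either. On the same scale as Kmt2a, the MLL fusion targets Hoxa9, Meis1 and Myb stood at 52.6 ± 4.76, 115 ± 13.6 and 603 ± 38.3 CPM in MA9 mock. In WT mock they stood at 0.061 ± 0.106, 4.41 ± 0.895 and 21.6 ± 3.33 CPM. Of 28 MLL fusion targets 24 were higher in every MA9 mock library than in any WT mock library and 3 lower (17 and 4 with total counts). Exchangeable libraries would give 10% in both directions together, but these are not exchangeable, since genotype and table coincide. Of 23 mast cell and basophil genes 1 was higher and 22 lower, and of 11 stromal and endothelial genes 1 and 5. The share over all genes was not computed, so separation by itself does not mark the MLL fusion targets. Of 26 neutrophil genes 5 were higher and 20 lower in this sense (2 and 22 with total counts), and of 25 monocyte and macrophage genes 1 and 21 (1 and 23 with total counts). S100a9 stood at 158 ± 35.8 against 10360 ± 1215 CPM, and the lysozyme gene Lyz2 at 231.7 ± 80.8 against 21290 ± 1280 CPM (SD, n = 3 each). The primary granule genes Mpo and Elane stood at 1042 ± 107 against 264.7 ± 42.3 CPM and 314 ± 28.8 against 94.7 ± 4.74 CPM. F13a1 of the monocyte list stood at 429.9 ± 42.7 against 75.7 ± 16.4 CPM. Genotype and table coincide, so these differences were not tested.

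**Figure D2:**
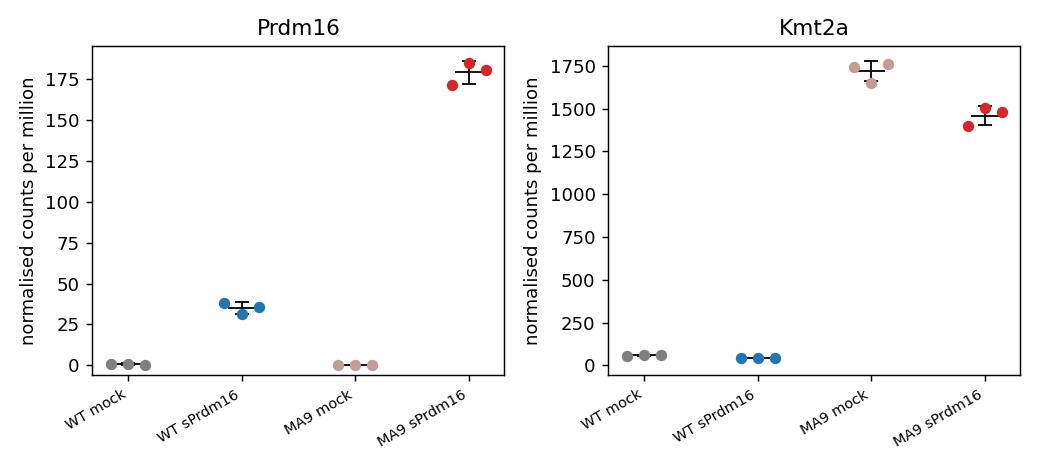
Normalised CPM (vertical axes, scaled over all 12 libraries) of Prdm16 and Kmt2a in the 4 groups (horizontal axes), with 1 point per library, the mean as a line and the SD as bars. Prdm16 is at 0 in the 3 MA9 mock libraries, and Kmt2a averages 1719 and 1460 CPM in the MA9 groups and 58.5 and 41.5 CPM in the WT groups.

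The first comparison asked what sPrdm16 changed in MLL::AF9 leukaemia cells. In the lists of carbon and lipid metabolism, the hypoxia response and glutathione defence that camera called, part of the genes rose, from 11 of 22 hypoxia genes to 13 of 15 fatty acid synthesis genes. Fatty acid oxidation, with 8 rises and 2 falls of 25, was not called. Of monocyte genes 14 of 19 fell, of eosinophil genes 8 of 11, of small nucleolar RNAs 169 of 183 and of mitochondrial genome transcripts 13 of 13. Camera called 16 lists with its preset correlation, and 0 of them held with an estimated one (smallest adjusted p = 0.172 with an estimated correlation). Inflammatory (8 of 20) and immediate early genes (12 of 22) also fell, relative to the median gene, and their medians were above 0 with total counts alone (0.80 and 0.81). After Prdm16, the largest rise in a protein-coding gene by the rule for named genes was that of Pitx1, a homeobox factor (ENSMUSG00000021506.7, chromosome 13, 55825051 to 55836192), from 1.09 ± 0.539 to 130 ± 3.74 CPM (log2 6.84, SE 0.18, adjusted p = 7.8e-08, n = 3 each). Next came the calcium channel gene Cacna1d (log2 5.76), the keratin gene Krt7 (5.71), the potassium channel gene Kcnq3 (5.59), the kinase gene Mast4 (4.10) and the kinase-anchoring scaffold gene Akap12 (3.57). Without MA9 mock replicate 3 the fitted value of Krt7 was 10.58. Snord22, a small nucleolar RNA at 0 in mock, was at least 26.5-fold higher. Among the largest falls were the kinase gene Pnck (log2 -7.78) and Plekha4 (-6.88), each with a wide spread in mock (138 ± 104 and 48.3 ± 25.4 CPM, SD, n = 3). With limma-voom the call of Pnck ended (adjusted p = 0.0589).

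In all, 2454 genes rose and 2525 fell of 14394 tested, 49.3% of the calls being rises, and 713 and 1201 did so by at least 2-fold. Scaled to total counts alone, 11489 rose and 607 fell (95.0% rises), with the median of all genes moved by 1.41 on the log2 scale, so directions in MA9 cells are relative to the median gene. A fit on all 12 libraries gave 59.5% rises (2803 and 1905). Without MA9 mock replicate 3 there were 3277 rises and 3225 falls. Without sPrdm16 replicates 1, 2 and 3 in turn, 1534, 1556 and 1606 genes rose, and the total without replicate 1 was 3306.

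The 13 protein-coding genes of the mitochondrial genome, all subunits of the respiratory chain or ATP synthase, fell together (13 of 13, also adjusted over the list alone), with a median log2 fold change of -3.59. Camera gave this list an adjusted p = 3.0e-08, and adjusted p = 0.379 with an estimated correlation. Examples were mt-Nd1 (ENSMUSG00000064341.1, mitochondrial positions 2751 to 3707, log2 -3.67, SE 0.43) and mt-Atp6 (-3.76, SE 0.42). The small nucleolar RNAs, which guide modification of ribosomal RNA, fell in 169 of 183 tested genes with a median of -3.60, and small nuclear RNAs in 175 of 188 with a median of -4.36. Snora28, within Eif5, was at 0 with sPrdm16 and at least 77.4-fold lower than in mock, and Snora33 (log2 -8.64), Snora81 (-8.62), Snora64 (-7.86), Snora36b (-7.30) and Snora23 (-6.81) also fell. The calls of Snora33 and Snora64 ended with limma-voom (adjusted p = 0.108 and 0.165), and their fitted values were -14.30 without MA9 sPrdm16 replicate 1 and -15.19 without replicate 2, respectively. These falls went with the fall of the structural RNA share from 63.7% to 18.2% of the counts. Mitochondrial ribosomal RNA stood at a median log2 fold change of -3.53 and the 7SL gene Rn7s1 at -3.39, near the mitochondrial genome list. With total counts the median of that list was -1.97. Respiratory chain subunits encoded in the nucleus did not pass the list test, with 2 rises and 2 falls among 36 members for complex I (camera adjusted p = 0.793) and 8 and 5 among 39 for complexes II to V (adjusted p = 0.642).

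Nuclear genes of central metabolism rose by small steps. Of 15 fatty acid synthesis genes 13 rose and 0 fell (13 and 0 adjusted over the list alone), with a median log2 fold change of 0.42 and camera adjusted p = 0.000136 (adjusted p = 0.172 with an estimated correlation). Fasn, fatty acid synthase (ENSMUSG00000025153.9, chromosome 11, 120805846 to 120824547), went from 315 ± 10.0 to 450 ± 12.7 CPM (log2 0.51, SE 0.05, adjusted p = 0.00012), and the desaturase gene Scd1 rose by 1.04 (SE 0.08). In cholesterol synthesis 12 of 23 rose and 1 fell (14 and 1 adjusted over the list alone, median 0.39, adjusted p = 0.00207, and adjusted p = 0.3 with an estimated correlation). Hmgcs1 rose by 0.88. The TCA cycle list had 15 rises and 1 fall of 27 (17 and 1 adjusted over the list alone, median 0.31, adjusted p = 0.00103, and adjusted p = 0.458 with an estimated correlation). Citrate synthase, Cs, rose by 0.48 and the succinyl-CoA ligase gene Suclg1 by 0.69. Glycolysis had 12 rises and 3 falls of 23 (13 and 3 adjusted over the list alone, median 0.32, adjusted p = 0.0269, and adjusted p = 0.3 with an estimated correlation). The hexokinase gene Hk3 rose by 0.76 and the pyruvate kinase gene Pkm by 0.45. In the pentose phosphate pathway, a source of NADPH and ribose, 5 of 7 rose and 0 fell (5 and 0 adjusted over the list alone, median 0.41, adjusted p = 0.0269, and adjusted p = 0.3 with an estimated correlation). Tkt rose by 0.63 and Rpia by 0.60.

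Glutathione and ROS defence genes rose in 14 of 27 and fell in 2 (16 and 2 adjusted over the list alone), with a median of 0.43 and camera adjusted p = 0.000968 (adjusted p = 0.3 with an estimated correlation). Gclm, a subunit of the enzyme that limits glutathione synthesis, rose by 1.09 (SE 0.09) and the peroxiredoxin gene Prdx5 by 0.76 (SE 0.08). Hypoxia genes rose in 11 of 22 and fell in 2 (11 and 2 adjusted over the list alone), with a median of 0.34 and adjusted p = 0.0038 (adjusted p = 0.197 with an estimated correlation). Egln3, a prolyl hydroxylase that acts on HIF (ENSMUSG00000035105.5, chromosome 12, 54178981 to 54203860), rose from 25.3 ± 3.84 to 107 ± 1.40 CPM (log2 2.10, SE 0.10, adjusted p = 2.4e-06, n = 3 each), and the mitophagy receptor gene Bnip3 by 0.97. Mitochondrial ribosome genes rose in 14 of 71 with 0 falls (8 and 0 adjusted over the list alone), with a median of 0.17 and adjusted p = 0.0323 (adjusted p = 0.591 with an estimated correlation). Mrpl34 (0.72) and Mrps12 (0.61) led this list, and their calls ended in libraries thinned to equal protein-coding depth (adjusted p = 0.107 and 0.0636). Both also ended without sPrdm16 replicate 2 (0.0564 and 0.0513), and that of Mrps12 without replicate 1 (0.0555). Of these calls, mitochondrial ribosome ended without mock replicate 1 (adjusted p = 0.416) and on nuclear protein-coding genes alone (adjusted p = 0.0822), and glycolysis and pentose phosphate ended without mock replicate 2 (adjusted p = 0.0599 and 0.0712). With total counts alone glycolysis, pentose phosphate, cholesterol synthesis and hypoxia lost the call (adjusted p = 0.107, 0.227, 0.0559 and 0.0955). Their medians were then 1.75, 1.87, 1.79 and 1.75, against the shift of 1.41 of all genes. Glycolysis also lost it without members shared with other lists (adjusted p = 0.0594).

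Markers of monocytes and macrophages fell in 14 of 19 tested genes and rose in 2 (14 and 2 adjusted over the list alone), with a median log2 fold change of -2.36 and camera adjusted p = 2.0e-06 (adjusted p = 0.379 with an estimated correlation). Csf1r, the receptor for macrophage colony-stimulating factor (ENSMUSG00000024621.16, chromosome 18, 61100598 to 61132149), fell from 17.4 ± 5.91 to 1.98 ± 0.293 CPM (log2 -3.11, SE 0.26, adjusted p = 3.9e-05, n = 3 each). The monocyte transcription factor genes Irf8 and Klf4 fell by 2.15 and 4.31. Eosinophil genes fell in 8 of 11 with 0 rises (9 and 0 adjusted over the list alone), with a median of -3.23 and adjusted p = 3.7e-07 (adjusted p = 0.172 with an estimated correlation). The granule protein genes Ear2 and Epx stood at -6.38 (SE 0.42) and -3.76 (SE 0.17). Dendritic cell and MHC class II genes fell in 7 of 13 and rose in 1 (7 and 2 adjusted over the list alone), with a median of -1.08 and adjusted p = 0.0259 (adjusted p = 0.3 with an estimated correlation). Cd74, the MHC class II invariant chain, fell by 4.58 and the costimulatory gene Cd86 by 3.98, while the MHC class II gene H2-Ab1 stood at 0.86. Neutrophil granule genes had 9 rises and 6 falls of 25 (camera adjusted p = 0.642) and mast cell and basophil genes 0 and 4 of 9 (adjusted p = 0.0839). Without mock replicate 3 the dendritic cell call ended (adjusted p = 0.107), and with total counts its median was 0.31 and the call of Irf8 ended (adjusted p = 0.0563).

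Inflammatory and immediate early genes fell as well. NF-kB and inflammatory genes fell in 8 of 20 and rose in 3 (11 and 3 adjusted over the list alone), with a median of -0.60 and camera adjusted p = 0.00851 (adjusted p = 0.3 with an estimated correlation). The inflammasome gene Nlrp3 fell by 1.72, and the chemokine gene Ccl2 had 83 counts in the mock group and 1 with sPrdm16, a normalised ratio of 286 with a counting interval of 49.9 to 11418. Immediate early and heat shock genes fell in 12 of 22 with 0 rises (13 and 0 adjusted over the list alone), with a median of -0.58 and adjusted p = 0.000683 (adjusted p = 0.3 with an estimated correlation). The transcription factor genes Atf3 and Egr2 stood at -3.07 and -3.44. p53 targets fell in 10 of 22 and rose in 1 (11 and 1 adjusted over the list alone), with a median of -0.46 and adjusted p = 0.000953 (adjusted p = 0.172 with an estimated correlation). Perp stood at -2.22 and the antiproliferative gene Btg2 at -1.24. In ribosome biogenesis and MYC 15 of 29 fell and 0 rose (17 and 0 adjusted over the list alone), with a median of -0.29 and adjusted p = 0.000953 (adjusted p = 0.172 with an estimated correlation). The nucleolar protein genes Ncl and Fbl fell by 0.77 (SE 0.06) and 0.87 (SE 0.08). With total counts the medians of these 4 lists were 0.80, 0.81, 0.96 and 1.13. The call held for immediate early genes alone, with adjusted p = 0.0955 for NF-kB, 0.244 for p53 targets and 0.873 for ribosome biogenesis. With total counts the calls of Perp and Nlrp3 ended (adjusted p = 0.0643 and 0.360), and Btg2, Ncl and Fbl turned to 0.18, 0.66 and 0.56.

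Genes that carry, activate or inactivate cytarabine did not move as a group in MA9 cells, with 6 rises and 3 falls among 17 tested (6 and 4 adjusted over the list alone, camera adjusted p = 0.793). Dck, deoxycytidine kinase, which activates the drug (ENSMUSG00000029366.10, chromosome 5, 88764996 to 88783281), fell from 31.0 ± 3.22 to 22.0 ± 0.922 CPM (log2 -0.49, SE 0.10, adjusted p = 0.0052, n = 3 each). Samhd1, which cleaves its triphosphate (ENSMUSG00000027639.16, chromosome 2, 157097533 to 157135265), rose from 28.9 ± 4.65 to 43.8 ± 0.226 CPM (log2 0.60, SE 0.11, adjusted p = 0.0032, n = 3 each). The nucleotidase genes Nt5c3 and Nt5c went opposite ways (log2 0.68 and -0.70). Of the ribonucleotide reductase genes Rrm2 rose by 0.33 and Rrm1 fell by 0.16. Slfn9 (0.51), the nucleoside diphosphate kinase gene Nme2 (0.50) and the dCMP deaminase gene Dctd (0.55) rose. The calls of Nme2, Rrm1 and Dctd each ended when any of the 3 sPrdm16 libraries was left out (adjusted p from 0.0730 to 0.0956, up to 0.176 and 0.119 to 0.158). They also ended without mock replicate 1 or 3 for Nme2 (0.0765 and 0.0511), mock replicate 2 for Rrm1 (0.0989) and mock replicate 1 for Dctd (0.0660). In the fit on all 12 libraries the calls of Dck, Rrm1 and Dctd ended (adjusted p = 0.0989, 0.646 and 0.101), and that of Rrm1 also with no filter (0.518). With GC and length offsets those of Rrm1, Dctd and Nme2 ended (0.0580, 0.0609 and 0.0898), and that of Dctd in libraries thinned to equal protein-coding depth (0.125). With total counts Dck, Nt5c and Rrm1 were higher with sPrdm16, by 0.94, 0.70 and 1.26.

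Other lists did not pass in MA9 cells. S phase genes had 9 rises and 6 falls of 30 (adjusted p = 0.793), G2 and M phase genes 9 and 2 of 30 (0.197), and DNA damage repair genes 4 and 3 of 30 (0.323). MLL fusion targets had 5 and 6 of 28 (0.311), blood stem cell genes 2 and 5 of 16 (0.208), and brown fat genes 3 and 4 of 15 (0.926). Fatty acid oxidation had 8 and 2 of 25 (0.0902) and nucleotide synthesis 6 and 1 of 22 (0.151). Given as rises, falls, members tested and camera adjusted p, the values were, for mitochondrial biogenesis 4 and 3 of 21 (0.908), ATF4 and amino acid stress 1 and 6 of 22 (0.0839), the PRDM and MECOM family 2 and 2 of 8 (0.79) and erythroid genes 1 and 1 of 6 (0.805). In the same form they were, for stromal and endothelial genes 2 and 2 of 7 (0.642), cyclins and CDK inhibitors 3 and 2 of 13 (0.793), the BCL2 family 6 and 4 of 23 (0.987) and TGF-beta signalling 2 and 5 of 19 (0.958). Further values were, for the cytosolic ribosome 16 and 18 of 77 (0.934), cytokine receptors 4 and 8 of 26 (0.319), chromatin and AML genes 7 and 4 of 25 (0.642) and lysosome and autophagy 5 and 7 of 26 (0.927). The remaining lists gave, for serine and one-carbon 1 and 4 of 14 (0.926), megakaryocyte genes 5 and 5 of 14 (0.793), interferon response 6 and 2 of 25 (0.275) and ABC transporters 2 and 5 of 16 (0.103). B cell genes (4 tested) and T and NK cell genes (2 tested) were too few for the list test. Of 45 lists tested camera called 16, with 15 of these also called by fry. With an estimated correlation 0 held, while 5 of the 16 had an unadjusted p under 0.05.

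The second comparison asked what sPrdm16 changed in normal bone marrow cells. Here cell cycle, DNA repair and nucleotide synthesis genes rose, and granule genes of neutrophils, mast cells and basophils fell, as lists that held with an estimated correlation (adjusted p = 0.0294 for each). Ribosome biogenesis genes also rose and eosinophil genes fell (28 of 30 and 10 of 11), with adjusted p = 0.0622 for each list with an estimated correlation. The embryonic globin gene Hbb-y (ENSMUSG00000052187.4, chromosome 7, 103851749 to 103853216) was at 0 in WT mock and 17.9 ± 1.88 CPM with sPrdm16 (at least 102-fold higher), and Ccdc102a was at least 37.5-fold higher. Septin3 (log2 4.62), the sphingosine receptor gene S1pr3 (4.39), the serine protease inhibitor gene Serpina3f (4.07), Plet1 (4.05) and Aff3 (3.85) followed. The largest falls were in Olfm4 (-6.85), the tryptase genes Tpsg1 (-6.83) and Tpsb2 (-5.94), the lipoxygenase gene Alox15 (-6.37), the mast cell chymase gene Cma1 (-5.69), Camp (-5.56), Krt83 (-5.49) and Skap1 (-5.36). Without WT sPrdm16 replicate 2 the fitted values of Tpsg1, Alox15 and Krt83 were -11.42, -10.96 and -9.53. Camp, the antimicrobial peptide cathelicidin (ENSMUSG00000038357.10, chromosome 9, 109847379 to 109849617), went from 364 ± 41.5 to 7.73 ± 0.484 CPM (SE 0.12, adjusted p = 3.2e-13, n = 3 each). In all, 2463 genes rose and 2335 fell of 14063 tested (51.3% rises), and 807 and 782 did so by at least 2-fold. With total counts 3668 rose and 1501 fell (71.0% rises), the median of all genes moving by 0.17.

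Genes of dividing cells rose in WT cells. S phase genes rose in 23 of 30 and G2 and M phase genes in 27 of 30, with 0 falls in either (23 and 28 rises adjusted over the list alone), with medians of 0.87 and 0.84 and camera adjusted p = 5.6e-09 and 9.7e-10. The replication helicase gene Mcm5 (ENSMUSG00000005410.6, chromosome 8, 75109569 to 75128439) rose from 50.8 ± 5.70 to 178 ± 12.8 CPM (log2 1.81, SE 0.11, adjusted p = 1.5e-08, n = 3 each) and Mcm2 by 1.51, and the mitotic kinase genes Aurkb and Plk1 rose by 1.17 and 1.12. DNA damage repair genes rose in 18 of 30 with 0 falls (19 adjusted over the list alone, median 0.75, adjusted p = 1.4e-07), such as Parp1 (1.32). Pyrimidine and purine synthesis genes rose in 16 of 22 with 0 falls (17 adjusted over the list alone, median 0.79, adjusted p = 1.4e-07), including Impdh2, which commits IMP to guanine nucleotides (1.77), and the thymidylate synthase gene Tyms (1.16). These 4 lists also passed with an estimated correlation (adjusted p = 0.0294 for each). Ribosome biogenesis and MYC genes rose in 28 of 30 with 0 falls (28 adjusted over the list alone, median 0.87, adjusted p = 8.1e-12, and adjusted p = 0.0622 with an estimated correlation). Myc itself (ENSMUSG00000022346.16, chromosome 15, 61985391 to 61990374) rose from 80.8 ± 9.14 to 244 ± 5.34 CPM (log2 1.59, SE 0.10, adjusted p = 2.0e-08, n = 3 each), and Nolc1 by 1.35. Serine and one-carbon genes rose in 11 of 13 with 0 falls (12 rises and 1 fall adjusted over the list alone, median 0.77, adjusted p = 5.3e-05, and adjusted p = 0.155 with an estimated correlation). Shmt1 rose by 2.15 and Shmt2 by 1.47.

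Genes of granule-bearing cells fell in WT cells. Mast cell and basophil genes fell in 20 of 23 and rose in 2 (20 and 2 adjusted over the list alone), with a median of -2.60 and camera adjusted p = 1.0e-13. The basophil protease gene Mcpt8 (ENSMUSG00000022157.8, chromosome 14, 56082166 to 56085273) fell by 3.94 (SE 0.09, adjusted p = 3.4e-13, n = 3 each), Prss34 by 5.27 and the carboxypeptidase gene Cpa3 by 3.14. Neutrophil granule and maturation genes fell in 18 of 26 and rose in 4 (18 and 5 adjusted over the list alone), with a median of -1.48 and adjusted p = 2.1e-07, among them the lactoferrin gene Ltf (-3.91) and Ngp (-4.35). Both lists also passed with an estimated correlation (adjusted p = 0.0294 for each). Eosinophil genes fell in 10 of 11 with 0 rises (10 adjusted over the list alone, median -2.31, adjusted p = 1.6e-08, and adjusted p = 0.0622 with an estimated correlation). The major basic protein gene Prg2 stood at -5.13 and Ear2 at -3.95. Monocyte and macrophage genes fell in 15 of 24 and rose in 3 (15 and 3 adjusted over the list alone, median -0.40, adjusted p = 0.00434, and adjusted p = 0.206 with an estimated correlation). The scavenger receptor gene Msr1 stood at -2.14. Megakaryocyte genes fell in 11 of 21 and rose in 4 (11 and 4 adjusted over the list alone, median -0.65, adjusted p = 0.0151, and adjusted p = 0.155 with an estimated correlation). Among them were platelet factor 4, Pf4 (-1.14), and Rab27b (-2.61), a secretion gene that the mast cell list also holds.

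Antigen presentation and interferon genes went the other way in WT cells. Dendritic cell and MHC class II genes rose in 10 of 19 with 0 falls (12 rises and 1 fall adjusted over the list alone), with a median of 0.92 and camera adjusted p = 5.3e-05 (adjusted p = 0.253 with an estimated correlation). The MHC class II gene H2-Ab1 (ENSMUSG00000073421.6, chromosome 17, 34257689 to 34269419) rose from 120 ± 9.72 to 621 ± 21.6 CPM (log2 2.37, SE 0.09, adjusted p = 8.3e-11, n = 3 each) and Cd74 by 1.71. Interferon response genes rose in 13 of 37 with 0 falls (17 adjusted over the list alone, median 0.66, adjusted p = 0.000121, and adjusted p = 0.0992 with an estimated correlation). Irf7 rose by 1.35 and Oas1a by 1.11. NF-kB and inflammatory genes fell in 16 of 28 and rose in 4 (16 and 4 adjusted over the list alone, median -0.79, adjusted p = 0.000132, and adjusted p = 0.0622 with an estimated correlation). Il1rn, which encodes a natural blocker of IL-1, stood at -2.46.

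Among metabolic lists in WT cells the TCA cycle rose in 13 of 27 and fell in 3 (14 and 3 adjusted over the list alone), with a median of 0.29 and camera adjusted p = 0.0117 (adjusted p = 0.206 with an estimated correlation). Idh2 rose by 1.16 and the mitochondrial pyruvate carrier gene Mpc1 fell by 0.79. The mitochondrial genome list fell in 9 of 13 with 0 rises (12 adjusted over the list alone, median -0.48, adjusted p = 0.00437, and adjusted p = 0.524 with an estimated correlation), with mt-Co1 at -0.73 (SE 0.11), while structural RNA was 2.25% ± 0.307 of the counts in WT mock and 1.72% ± 0.313 with sPrdm16 (SD, n = 3 each). Nuclear complex I genes fell in 14 of 36 and rose in 3 (14 and 3 adjusted over the list alone, median -0.18, adjusted p = 0.0427, and adjusted p = 0.612 with an estimated correlation). Ndufa2 stood at -0.61 and Ndufv1 at 0.72. The mitochondrial genome and complex I lists did not pass fry (adjusted p = 0.0898 and 0.0967), and the call of mt-Co1 ended in the fit on all 12 libraries (0.112). The complex I call ended with total counts (adjusted p = 0.217) and without mock replicate 2 or 3 or sPrdm16 replicate 1 or 2 (adjusted p = 0.0715, 0.0667, 0.142 and 0.0874). Glycolysis (11 rises and 4 falls of 24, adjusted p = 0.114), fatty acid synthesis (5 and 1 of 13, 0.0629), cholesterol synthesis (2 and 1 of 23, 0.691), hypoxia (7 and 6 of 21, 0.881) and glutathione defence (3 and 11 of 27, 0.0652) did not pass.

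Of 18 cytarabine genes tested in WT cells 5 rose and 5 fell (7 and 5 adjusted over the list alone, camera adjusted p = 0.444). Rrm1, Rrm2, Dctd, the thymidine kinase gene Tk1 and the nucleoside transporter gene Slc29a2 rose by 0.98, 0.76, 2.49, 1.07 and 2.15. Dck, Samhd1, Nt5c3, the UMP/CMP kinase gene Cmpk1 and Rrm2b fell by 0.84, 0.57, 0.48, 0.85 and 0.70. The fall of Rrm2b ended without mock replicate 1 or 3 or any 1 sPrdm16 library (adjusted p from 0.0532 to 0.163), with total counts (0.108) and with GC and length offsets (0.124). That of Nt5c3 ended with total counts (0.0638). Other lists that did not pass in WT cells gave, as rises, falls, members tested and camera adjusted p, for mitochondrial biogenesis 7 and 2 of 21 (0.0844), ATF4 and amino acid stress 9 and 4 of 22 (0.314), the PRDM and MECOM family 2 and 1 of 9 (0.324) and erythroid genes 6 and 3 of 18 (0.451). Likewise the values were, for stromal and endothelial genes 4 and 3 of 9 (0.426), cyclins and CDK inhibitors 3 and 9 of 16 (0.0946), the BCL2 family 3 and 7 of 23 (0.194) and TGF-beta signalling 5 and 5 of 19 (0.889). Similarly, they were, for the cytosolic ribosome 20 and 2 of 77 (0.139), cytokine receptors 9 and 9 of 27 (0.76), chromatin and AML genes 6 and 3 of 25 (0.335) and lysosome and autophagy 2 and 9 of 26 (0.0717). Metabolic lists among them gave, for nuclear complexes II to V 7 and 17 of 39 (0.178), mitochondrial ribosome 16 and 8 of 71 (0.0957), pentose phosphate 0 and 4 of 7 (0.125) and fatty acid oxidation 7 and 3 of 26 (0.25). Stem and lineage lists gave, for brown fat genes 1 and 1 of 15 (0.427), MLL fusion targets 6 and 5 of 19 (0.933), blood stem cell genes 7 and 3 of 22 (0.426) and B cell genes 2 and 1 of 6 (0.426). The last of them gave, for T and NK cell genes 2 and 0 of 7 (0.0629), p53 targets 3 and 10 of 22 (0.061), ABC transporters 5 and 1 of 18 (0.25) and immediate early genes 5 and 8 of 23 (0.427). Of 47 lists camera called 17, of which 6 held with an estimated correlation.

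**Figure D3:**
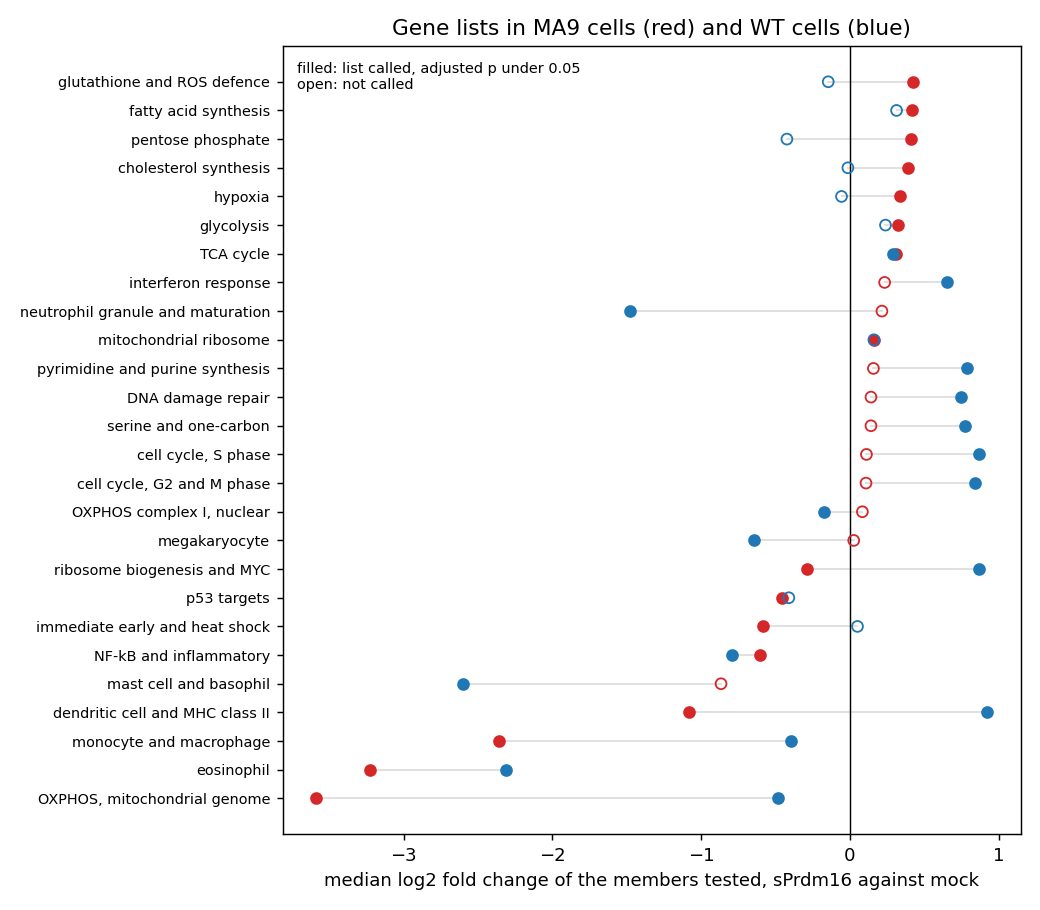
Median log2 fold change of sPrdm16 against mock (horizontal axis) over the tested members of each gene list called in at least 1 genotype (vertical axis), in MA9 cells (red) and WT cells (blue), filled where camera called the list and open where it did not. Ribosome biogenesis lies at -0.29 in MA9 and 0.87 in WT cells, and the MA9 median turns to 1.13 with total counts.

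The interaction asked whether the response to sPrdm16 differed between the genotypes, and 2588 genes had a higher and 1945 a lower log2 fold change in MA9 than in WT cells, of 16194 tested (57.1% higher). Scaled over all 12 libraries, Prdm16 averaged 179 ± 6.92 CPM in MA9 sPrdm16 and 35.0 ± 3.50 CPM in WT sPrdm16 (SD, n = 3 each). A difference between genotypes therefore cannot be told apart from one in Prdm16 level or growth medium, which the labels give for MA9 cells alone. Nor can it be told apart from the shift in RNA classes between the MA9 groups. Relative to the median gene, cell cycle, ribosome biogenesis and nucleotide synthesis genes responded less positively in MA9 cells, and with total counts alone their median differences were above 0. Dendritic cell and MHC class II genes responded less positively as well, with a median difference of -1.14 that shrank to -0.11 with total counts. The glutathione and pentose phosphate lists responded more positively in MA9 cells, with median differences of 1.03 and 0.69. GC and length offsets gave 46.8% higher calls, and total counts alone 96.0% (8177 higher and 342 lower), with the median of all genes moved by 1.15. The largest differences were in Lama5 (10.94), Hmgn3 (9.65), Prdm16 (9.22) and Grk3 (7.35), and in Ctnnd2 (-10.19), Synpo (-7.66), Flrt3 (-6.89) and Ccl2 (-6.82). Lama5, Hmgn3, Grk3 and Prdm16 had 0 counts in MA9 mock, and Synpo and Flrt3 had 0 in MA9 sPrdm16, so their fitted values depend on the prior count. Ctnnd2, a catenin gene, had 74 counts in MA9 mock and 2 with sPrdm16 (normalised ratio 127, counting interval 34.0 to 1071), and rose by 3.58 in WT cells.

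Ribosome biogenesis and MYC genes had lower responses in MA9 than in WT cells in 28 of 30 with 0 higher (28 and 0 adjusted over the list alone, median difference -1.15, camera adjusted p = 7.3e-15, and adjusted p = 0.0109 with an estimated correlation). Myc differed by -1.40 (SE 0.13) and Fbl by -1.67 (SE 0.16). S phase genes were lower in 20 of 30 and higher in 1 (22 and 2 adjusted over the list alone, median -0.80, adjusted p = 2.1e-07, and adjusted p = 0.0306 with an estimated correlation). Mcm2 differed by -1.57. G2 and M phase genes were lower in 19 of 30 with 0 higher (20 and 1 adjusted over the list alone, median -0.63, adjusted p = 1.7e-05, and adjusted p = 0.0469 with an estimated correlation). Bub1b differed by -1.37. DNA damage repair genes were lower in 15 of 30 and higher in 1 (15 and 1 adjusted over the list alone, median -0.60, adjusted p = 0.000186, and adjusted p = 0.0182 with an estimated correlation). Parp1 differed by -1.16. Pyrimidine and purine synthesis was lower in 14 of 22 and higher in 1 (16 and 2 adjusted over the list alone, median -0.61, adjusted p = 0.0002, and adjusted p = 0.0412 with an estimated correlation). Impdh2 differed by -1.38. Serine and one-carbon was lower in 9 of 14 and higher in 1 (9 and 1 adjusted over the list alone, median -0.74, adjusted p = 0.000621, and adjusted p = 0.0505 with an estimated correlation). Shmt2 differed by -1.62. With total counts the medians of these 6 lists were 0.024, 0.34, 0.53, 0.53, 0.54 and 0.42, and the calls of all but ribosome biogenesis ended (adjusted p = 0.0769, 0.649, 0.196, 0.514 and 0.182). The calls of the 7 example genes ended as well (adjusted p at least 0.190), with Parp1 turned to 0.0035.

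Glutathione and ROS defence responded more positively in MA9 cells in 18 of 27 and less in 1 (18 and 1 adjusted over the list alone, median difference 1.03, camera adjusted p = 5.1e-06, and adjusted p = 0.0236 with an estimated correlation). Prdx5 differed by 2.13 and Gclm by 1.32. Pentose phosphate did so in 6 of 7 with 0 lower (6 and 0 adjusted over the list alone, median 0.69, adjusted p = 0.00231, and adjusted p = 0.0412 with an estimated correlation). Rpia differed by 1.45. Hypoxia was higher in 7 of 22 and lower in 1 (7 and 1 adjusted over the list alone, median 0.32, adjusted p = 0.0293, and adjusted p = 0.214 with an estimated correlation). Ero1l differed by 2.06. On genes tested within both genotypes the hypoxia call ended (adjusted p = 0.0802). Cholesterol synthesis was higher in 8 of 23 and lower in 1 (10 and 1 adjusted over the list alone, median 0.28, adjusted p = 0.0461, and adjusted p = 0.116 with an estimated correlation). Hmgcs1 differed by 1.16. The cholesterol call ended on those genes (adjusted p = 0.0736), with RLE scaling (0.0614) and without MA9 mock replicate 1 or 2, WT mock replicate 1 or WT sPrdm16 replicate 1 (adjusted p = 0.0644, 0.0808, 0.0553 and 0.0536).

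Neutrophil genes were higher in 15 of 26 and lower in 3 (18 and 4 adjusted over the list alone, median difference 1.23, camera adjusted p = 1.2e-05, and adjusted p = 0.0109 with an estimated correlation). The list medians were 0.22 in MA9 and -1.48 in WT cells. In the mock libraries 20 of the 26 were lower in MA9 than in WT and 5 higher. Ltf, for example, stood at 1.74 against 1011 CPM, which left little room for a fall in MA9 cells. The calprotectin gene S100a9 rose by 1.89 in MA9 cells (SE 0.15, adjusted p = 5.1e-05) and fell by 2.67 in WT cells, a difference of 4.65 (SE 0.20), while Ngp fell in both and differed by 3.32. Mast cell and basophil genes were higher in 7 of 23 and lower in 2 (7 and 2 adjusted over the list alone, median 3.13, adjusted p = 2.5e-10, and adjusted p = 0.00792 with an estimated correlation). Mcpt8 differed by 4.26. Of these 23 genes 11 had 0 counts in MA9 mock and 9 of them in all MA9 libraries, so for those 9 the difference reflects WT counts alone. Over the 9 members tested within both genotypes 5 were higher and 1 lower, with a median difference of 0.72 between medians of -0.87 in MA9 and -1.52 in WT cells. On genes tested within both, a choice made after seeing the data, camera gave this list adjusted p = 0.0430, and adjusted p = 0.174 with an estimated correlation. Monocyte genes were lower in 15 of 25 and higher in 3 (16 and 3 adjusted over the list alone, median -2.16, adjusted p = 0.000186, and adjusted p = 0.31 with an estimated correlation). Csf1r differed by -3.29. Dendritic cell and MHC class II genes were lower in 9 of 20 and higher in 2 (9 and 2 adjusted over the list alone, median -1.14, adjusted p = 9.9e-07, and adjusted p = 0.0236 with an estimated correlation). Cd74 differed by -6.16. Immediate early genes were lower in 10 of 23 and higher in 1 (11 and 1 adjusted over the list alone, median -0.52, adjusted p = 0.00999, and adjusted p = 0.255 with an estimated correlation). Atf3 differed by -3.36. ABC transporters were lower in 6 of 19 and higher in 1 (7 and 1 adjusted over the list alone, median -0.52, adjusted p = 0.034, and adjusted p = 0.214 with an estimated correlation). The drug efflux genes Abcg2 and Abcb1b differed by -4.31 and -5.78. Abcb1b had 12 counts in MA9 mock and 1 with sPrdm16 (normalised ratio 41.3, counting interval 6.11 to 1766). The ABC transporter call ended without WT sPrdm16 replicate 1 (adjusted p = 0.0618) and on genes tested within both genotypes (0.0802), and with total counts it and the immediate early call ended (adjusted p = 0.0562 and 0.257) with medians of 0.68 and 0.67.

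The mitochondrial genome list was lower in 13 of 13 (13 and 0 adjusted over the list alone, median difference -3.11, camera adjusted p = 4.2e-09, and adjusted p = 0.255 with an estimated correlation), with mt-Nd1 at -3.46, beside a fall of the structural RNA share with sPrdm16 from 63.7% to 18.2% in MA9 and from 2.25% to 1.72% in WT. With total counts the median difference of this list was -1.77. Of 18 cytarabine genes the response was higher in MA9 cells for Samhd1 (1.26, SE 0.15, adjusted p = 5.1e-06), Nt5c3 (1.23) and Cmpk1 (0.96). It was lower for Rrm1 (-1.06, SE 0.14), Tk1 (-1.12), Dctd (-1.85), Nt5c (-0.54), Slc29a2 (-2.32), Rrm2 (-0.35) and Slc29a1 (-0.63), and the list did not pass (3 higher and 7 lower, also adjusted over the list alone, camera adjusted p = 0.693). Samhd1 and Nt5c3 rose in MA9 and fell in WT cells. With total counts Rrm1, Tk1, Nt5c, Rrm2 and Slc29a1 turned to positive differences of 0.10, 0.051, 0.61, 0.82 and 0.50, and the calls of Dctd and Slc29a2 ended (adjusted p = 0.27 and 0.23). The calls of 4 of these genes ended without single libraries. Those of Slc29a1 were MA9 mock replicate 2 (adjusted p = 0.185), WT mock replicates 2 and 3 (0.104 and 0.0518) and each sPrdm16 library of either genotype (0.0649 to 0.114). Those of Rrm2 were MA9 mock replicate 2, WT mock replicates 2 and 3, WT sPrdm16 replicates 1 and 2 and each MA9 sPrdm16 library (0.0591 to 0.110). Those of Slc29a2 were MA9 mock replicate 2 (0.0982), MA9 sPrdm16 replicates 1 and 2, WT mock replicates 2 and 3 and WT sPrdm16 replicate 2 (0.0503 to 0.0793). Those of Nt5c were MA9 sPrdm16 replicates 1 and 2 and WT sPrdm16 replicate 3 (0.0515, 0.0519 and 0.0530). With no filter the calls of Slc29a1, Rrm2 and Nt5c ended (adjusted p = 0.0651, 0.346 and 0.0719), and with limma-voom that of Slc29a1 (0.0543).

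**Figure D4:**
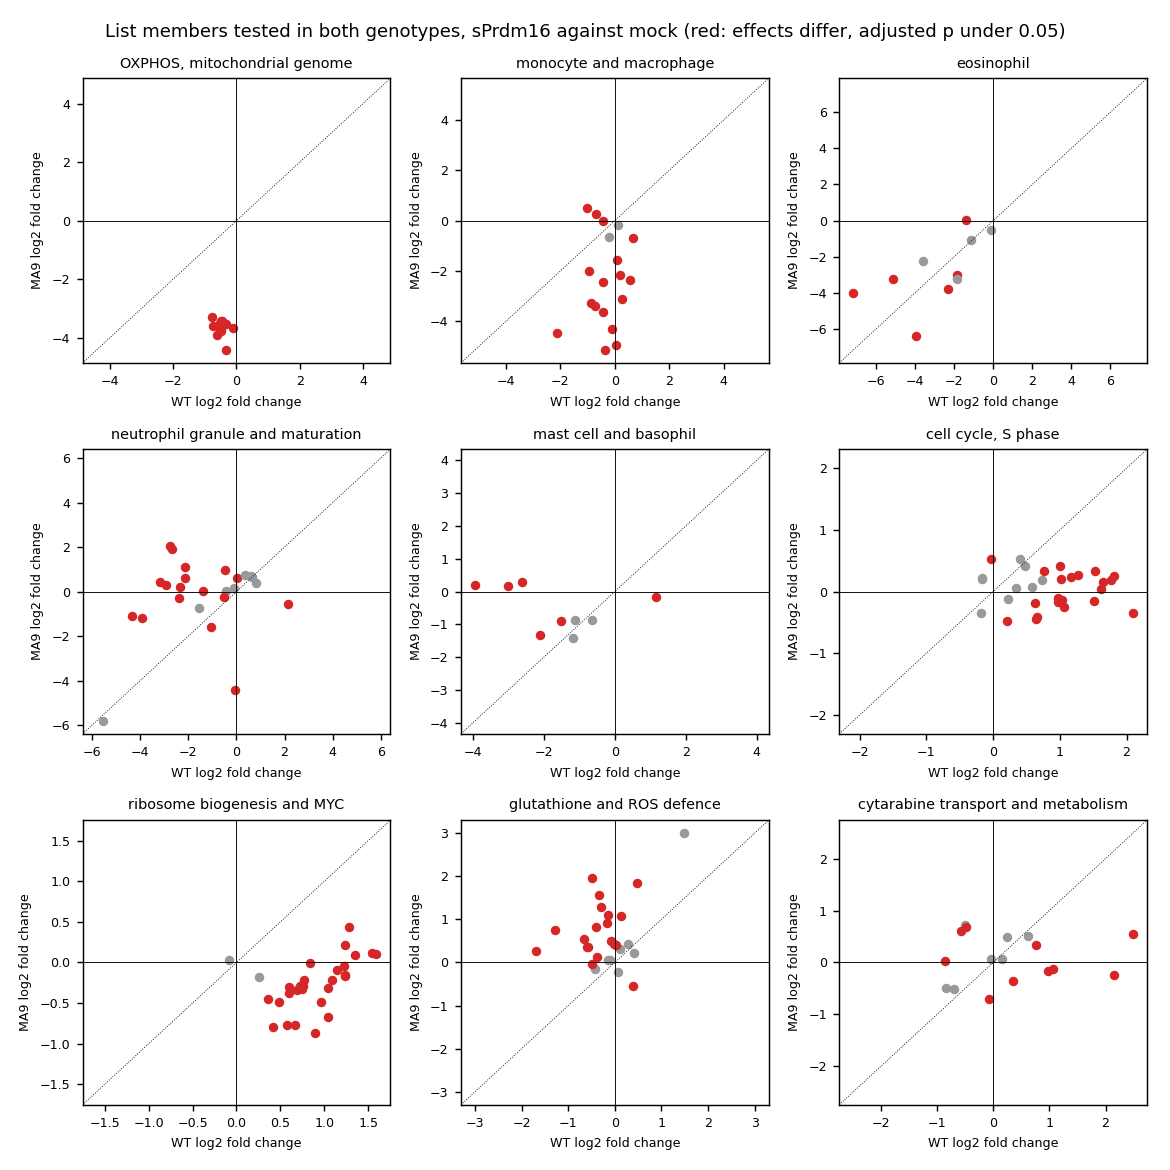
Log2 fold change of sPrdm16 against mock in WT cells (horizontal axes) and MA9 cells (vertical axes) for each gene of 9 lists that was tested in both, with red points where the 2 effects differ by the interaction test at adjusted p under 0.05, grey points otherwise and equal effects on the dotted line. The 13 genes of the mitochondrial genome lie near -3.59 in MA9 cells, and ribosome biogenesis genes lie mostly right of 0 in WT and below 0 in MA9 cells, the latter turning above 0 (median 1.13) with total counts.

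Calls in the 2 genotypes overlapped in the same direction more than independent lists would. Among 12373 genes tested in both, 515 rose in both against 420.5 from independent lists (odds ratio 1.37, 95% interval 1.23 to 1.54, Fisher's exact test, adjusted p = 6.1e-08). A further 488 fell in both against 315.9 (odds ratio 1.96, interval 1.74 to 2.20, Fisher's exact test, adjusted p = 2.1e-27). Opposite calls were near the independent number, with 394 against 378 for rises in MA9 and falls in WT (adjusted p = 0.319) and 330 against 351 for the reverse (adjusted p = 0.237, both Fisher's exact tests). These tests take genes as independent units, which they are not, so their p-values and intervals do not measure the spread between libraries. Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.15 and a Spearman correlation of 0.094. Prdm16 rose in both, and Ear2, Epx, Prg2, Msr1 and Perp fell in both.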

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

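Of the tests in this part, the GC and length offsets, the thinning, the spread test of mast cell genes and the list tests on genes tested within both genotypes were chosen after the result was seen, as was the widening of the histone set. A result is given here because the test of the difference between genotypes passed at an adjusted p under 0.05, and each value is the log2 fold change in MA9 cells minus that in WT cells, as a median for a list. Lists with a lower response in MA9 cells were OXPHOS, mitochondrial genome (-3.11), monocyte and macrophage (-2.16), dendritic cell and MHC class II (-1.14), ribosome biogenesis and MYC (-1.15) and immediate early and heat shock (-0.52), and further pyrimidine and purine synthesis (-0.61), serine and one-carbon (-0.74), cell cycle, S phase (-0.80), cell cycle, G2 and M phase (-0.63), DNA damage repair (-0.60) and ABC transporters (-0.52). Lists with a higher response in MA9 cells were pentose phosphate (0.69), cholesterol synthesis (0.28), glutathione and ROS defence (1.03), hypoxia (0.32), neutrophil granule and maturation (1.23) and mast cell and basophil (3.13). Of these 17 lists 10 held with an estimated correlation. The others gave adjusted p = 0.255 for the mitochondrial genome, 0.310 for monocyte, 0.255 for immediate early, 0.214 for ABC transporter, 0.214 for hypoxia, 0.116 for cholesterol and 0.0505 for serine and one-carbon genes. The mast cell value rests largely on WT cells, since 11 of its 23 members had 0 counts in MA9 mock, and over the 9 members tested within both genotypes the median difference was 0.72 (adjusted p = 0.0430, and adjusted p = 0.174 with an estimated correlation). With total counts alone the medians of nucleotide synthesis, serine and one-carbon, S phase, G2 and M phase, repair, ABC transporters, ribosome biogenesis and immediate early genes turned positive.

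Among metabolic genes the difference was positive for Scd1 (0.75), Gclm (1.32), Prdx5 (2.13), Egln3 (1.05), Bnip3 (1.12), Tkt (0.51), Rpia (1.45), Hmgcs1 (1.16) and Ero1l (2.06), and for the mitochondrial genes Mrpl34 (0.83), Mrps12 (0.78), Ndufa2 (1.16) and Mpc1 (1.30). It was negative for Fasn (-0.73), Ndufv1 (-0.71), mt-Nd1 (-3.46), mt-Atp6 (-3.14) and mt-Co1 (-2.77). Without WT mock replicate 1 the call of Scd1 ended (adjusted p = 0.0603). Genes of nucleotide and cytarabine metabolism gave Samhd1 (1.26), Nt5c3 (1.23), Cmpk1 (0.96), Nt5c (-0.54), Rrm1 (-1.06), Rrm2 (-0.35), Dctd (-1.85), Tk1 (-1.12), Slc29a1 (-0.63), Slc29a2 (-2.32), Impdh2 (-1.38), Tyms (-0.85), Shmt1 (-1.78) and Shmt2 (-1.62). Genes of division, repair and ribosome biogenesis gave Mcm5 (-1.48), Mcm2 (-1.57), Aurkb (-0.75), Plk1 (-0.70), Bub1b (-1.37), Parp1 (-1.16), Myc (-1.40), Nolc1 (-1.18), Ncl (-1.27) and Fbl (-1.67). Without MA9 mock replicate 2 the call of Aurkb ended (adjusted p = 0.0532). With total counts alone Fasn, Ndufv1, Nt5c, Rrm1, Rrm2, Tk1, Slc29a1, Tyms, Aurkb, Plk1, Parp1 and Nolc1 turned positive, and of these only Rrm2 passed the test in that direction. The calls of Dctd, Slc29a2, Impdh2, Shmt1, Shmt2, Mcm5, Mcm2, Bub1b, Myc, Ncl and Fbl ended under the same scaling.

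Among lineage genes the difference was negative for Csf1r (-3.29), Irf8 (-2.25), Klf4 (-4.17), Msr1 (-2.26), Epx (-1.37), Ear2 (-2.35), Cd74 (-6.16), Cd86 (-3.96) and H2-Ab1 (-1.42). It was positive for S100a9 (4.65), Ngp (3.32), Ltf (2.81), Olfm4 (6.19), Mcpt8 (4.26), Prg2 (1.99) and Pf4 (1.18). Inflammatory, interferon and stress genes gave Ccl2 (-6.82), Nlrp3 (-0.92), Il1rn (1.74), Irf7 (-1.06), Oas1a (-0.86), Atf3 (-3.36), Egr2 (-2.71), Perp (-0.96), Btg2 (-0.68) and Abcg2 (-4.31). Other genes were Cacna1d (6.92), Mast4 (3.24), Plekha4 (-4.69), S1pr3 (-2.90), Serpina3f (-3.86), Plet1 (-3.93) and Ctnnd2 (-10.19). The fitted values of Prdm16 (9.22), Lama5 (10.94), Hmgn3 (9.65), Grk3 (7.35), Synpo (-7.66) and Flrt3 (-6.89) depend on the prior count, because each had an MA9 group at 0. With total counts alone Nlrp3, Irf7, Oas1a, Perp and Btg2 turned positive without passing the test, and the calls of Epx, Ear2, H2-Ab1 and S1pr3 ended. Leaving out any 1 library other than MA9 mock replicate 3, MA9 sPrdm16 replicate 2 and WT mock replicate 2 ended the call of Irf7 (adjusted p up to 0.226). That of Oas1a ended without MA9 mock replicate 1 (adjusted p = 0.0987), MA9 sPrdm16 replicate 1 (0.0598) or WT sPrdm16 replicate 3 (0.0674). Without WT sPrdm16 replicate 2 the calls of Epx (-0.86, adjusted p = 0.0916) and Plekha4 (-4.01, adjusted p = 0.0528) ended, and without WT mock replicate 2 S1pr3 moved to -4.85. With limma-voom the calls of Irf7 and Oas1a ended (adjusted p = 0.170 and 0.0577), with no filter and with GC and length offsets that of Irf7 (0.0542 and 0.0507), and with these offsets that of Pf4 (0.108).

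The first pattern weighed was the lower structural and mitochondrial RNA in MA9 sPrdm16 libraries. More capture of RNA without poly(A) tails in the mock libraries would lower histone genes with sPrdm16, but 64 histone genes had a median log2 fold change of 0.480, with 36 rises and 2 falls. This argues against such capture for the histone genes and does not exclude it for other RNAs. Whether the difference came from the cells or from library preparation stays open and was not tested further, since preparation by group is not given in the sources used here.

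The second pattern was the set of MA9 calls among nuclear protein-coding genes. If the structural RNA share set them, mock replicates 3 and 1 would differ along the same genes with a slope of 0.421, and the slope was 0.0699 (SE 0.00690). It was taken over called genes alone, and calling favours genes whose mock libraries agree. The lower slope therefore cannot decide whether the share set the calls, and its SE takes genes as independent. With GC and length offsets 91.8% of these calls stayed in the same direction, which argues against those trends as the whole cause. After thinning to equal protein-coding depth 76.4% stayed, so a part that rests on depth cannot be told apart from calls lost with fewer counts. An effect of sPrdm16 on these genes remains a hypothesis.

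The third pattern was the fall of mast cell, basophil and granulocyte genes in WT cells. With GC and length offsets 100% of 47 falling members stayed called, against those trends as the cause. A lower share of 1 mast cell or basophil population of unchanged makeup would move its restricted genes alike, but 6 of them ranged from -5.27 to -3.02, an SD of 7.99 times their median SE. Hdc (-2.10), which would raise this to 10.2, was left out because it stood at 127.8 CPM in MA9 mock. The genes and the limit were set after the values were seen. Some expression outside that population would also make the falls unequal, so the spread cannot decide whether its share fell. A shift among several populations, or lower expression within cells, may each contribute and was not tested.

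In MA9 cells 4979 genes were called, 1 of the 10 splits of the 6 libraries gave as many, and the highest other split gave 0 by edgeR, the only tool run on splits, with 51 to 171 genes at unadjusted p under 0.05. In WT cells the values were 4798 and 0, with 117 to 283 genes at unadjusted p under 0.05 in the other splits. Called lists numbered 16 with 9 in the highest other split in MA9 cells, and 17 with 14 in WT cells. For all 4 counts 10 splits are too few for a share under 0.05. For the difference between genotypes 1 of 100 drawn splits gave as many as 4533 genes, which was the true grouping, the highest other being 1090. Each other split with a called gene kept the true groups of 1 genotype, and splits that mixed the groups in both gave 0 genes. Such splits break the sPrdm16 effect within a genotype, so they cannot decide how many calls equal effects would give. For its 17 lists 8 of 100 gave as many, with 20 the highest other. All 8 kept the true groups of at least 1 genotype, and splits that mixed the groups in both gave at most 16 lists. These splits therefore cannot decide whether chance gives as many lists, and chance is not excluded.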

How the results depend on the processing

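The fit on nuclear protein-coding genes, GC and length offsets, thinning, list tests on genes tested within both genotypes and other scalings of mock levels were tests chosen after the result was seen, and the others were planned. With total counts alone, MA9 calls were 12096 (11489 rises, 607 falls), interaction calls 8519 (8177 higher, 342 lower), and WT falls 1501. Against a fold of 1.5 there were 1637 calls in MA9 (610 and 1027), 1286 in WT (642 and 644) and 1790 for the interaction (966 and 824). The stricter null shows the cause of the latter, and the cause of the former was not tested beyond the shift of all genes by 1.41, 0.17 and 1.15. Beside the MA9 shift, nuclear protein-coding genes averaged 28.2% of the counts in MA9 mock and 75.5% in MA9 sPrdm16. The fit on nuclear protein-coding genes kept 3772 of the 3923 MA9 calls tested in it (96.2%) and reversed 0. With total counts these MA9 log2 values reversed: Nt5c 0.70, Dck 0.94, Rrm1 1.26, Btg2 0.18, Ncl 0.66 and Fbl 0.56. Of 82 genes named with a called difference between genotypes, 17 reversed, which were Rrm1 0.10, Tk1 0.051, Nt5c 0.61, Rrm2 0.82, Slc29a1 0.50, Parp1 0.0035, Fasn 0.43, Nlrp3 0.21, Perp 0.20, Btg2 0.48, Aurkb 0.38, Plk1 0.46, Nolc1 0.012, Tyms 0.29, Irf7 0.055, Oas1a 0.26 and Ndufv1 0.44, and a further 15 lost their call. The MA9 ribosome biogenesis list reversed with adjusted p = 0.873. Mock levels in MA9 against WT moved to log2 3.61 for Kmt2a, 3.77 for Hoxa9 and 3.06 for Meis1.

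Called lists in MA9, WT and the interaction numbered 0, 6 and 10 with an estimated correlation, where by camera 5, 12 and 12 lists had an unadjusted p under 0.05. They numbered 28, 33 and 31 with fry, 44, 46 and 47 with its mixed test, and 9 in MA9 with total counts. Leaving out 1 library gave 3306 to 6502 MA9 calls (1534 to 3277 rises, 1772 to 3225 falls), 3610 to 4526 in WT (1832 to 2391 rises, 1778 to 2135 falls) and 3649 to 4671 for the interaction (2137 to 2680 higher, 1506 to 1991 lower). Lists numbered 14 to 16, 16 to 20 and 15 to 19. The replicate block gave 4193, 4631 and 4136 calls, and the numbers do not pair the samples, since same-number correlations were -0.15, -0.015 and -0.13 in MA9 and 0.14, 0.0025 and -0.038 in WT, and not every library correlated best with its own number. Over all settings, named genes stayed the same in 1001 of 1059 cases in MA9, 1020 of 1038 in WT and 1769 of 1876 for the interaction, and called lists in 193 of 223, 218 of 237 and 332 of 356. Depth limits MA9 mock values most, at 3844558 to 7406093 nuclear protein-coding counts.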

Other observations

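The tests of KEGG terms, whose names the deposited tables give per gene, were chosen after the result was seen. In MA9 cells camera called 19 of 305 terms. Carbon metabolism had 39 rises and 5 falls of 94 genes (median log2 0.28, adjusted p = 0.00156), starch and sucrose metabolism 15 and 2 of 20 (0.49, adjusted p = 0.00156), and butanoate metabolism 9 and 0 of 13 (0.60, adjusted p = 0.00156). Valine, leucine and isoleucine degradation had 18 and 1 of 43 (0.32, adjusted p = 0.00488), and protein processing in the endoplasmic reticulum 56 and 15 of 147 (0.17, adjusted p = 0.0494). Protein digestion and absorption had 3 and 15 of 24 (-0.63, adjusted p = 0.00315). Each of these MA9 calls was lost, at adjusted p = 0.784 with an estimated correlation.

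In WT cells camera called 73 of 309 terms. DNA replication had 23 rises and 2 falls of 35 genes (median 0.65, adjusted p = 2.6e-06, and adjusted p = 0.323 with an estimated correlation), and aminoacyl-tRNA biosynthesis 30 and 1 of 44 (0.55, adjusted p = 2.6e-06, and adjusted p = 0.347 with an estimated correlation). Cytokine and receptor genes had 11 and 50 of 121 (-0.29, adjusted p = 0.000326, and adjusted p = 0.323 with an estimated correlation). For the difference between genotypes 19 of 309 terms were called. Leukocyte transendothelial migration was higher in MA9 cells for 38 and lower for 7 of 76 genes (median 0.47, adjusted p = 0.00599, and adjusted p = 0.438 with an estimated correlation), and aminoacyl-tRNA biosynthesis lower for 19 with 0 higher of 44 (-0.52, adjusted p = 3.4e-05, and adjusted p = 0.438 with an estimated correlation). Values under total counts alone were not computed for these terms.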
